A study of Mus musculus with 66 samples.

How the data were processed

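The 66 samples are mouse RNA: 50 gene-count libraries in 25 groups of 2, and 16 targeted libraries of Nr2f1 or Foxa1. The count values were made by the authors as whole fragments per gene and deposited without normalization. Per the file headers, featureCounts 1.5.1 counted reverse-stranded fragments (strand setting 2) over whole gene bodies, introns included, with GENCODE vM13 on mm10. Chimeric pairs were left out, mapping quality was at least 10, and a fragment was counted for every gene it overlapped. The alignment names in the headers show that ribosomal RNA reads were removed first. Per the labels' protocols, libraries came from a TruSeq Stranded mRNA kit, or a TruSeq Stranded Total RNA kit for the knockout experiments in lines A and B. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.4.4 and aligned with Bowtie2 2.2.9, with TopHat2 2.1.1 also listed for some samples. Each of the 8 induction samples has a second count file, with 95.2 to 96.7% of the first file's total, whose aligner is not stated in the sources used here. The file named like those of the other experiments was used, and the second as an alternative. The targeted files, as deposited, give read counts of the wild-type sequence and of 2 mutant sequences.

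Each count file holds 50600 gene models, of which 50376 (99.6%) have a symbol in GENCODE vM21. Total counts per library ran from 12.5 to 56.0 M. Groups and replicate numbers come from the labels alone. No pair of replicates was a duplicate: the chi-square per gene between replicates ran from 3.86 to 139, where counting noise alone gives about 1. The labels do not say whether replicates were separate cultures, so the p-values hold for these samples. The main comparisons, tests, filters, gene lists and most alternatives were fixed before the data were examined.

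Each of 7 experiments with control, loss and return groups (6 libraries) was fitted alone in edgeR 4.0.16 (R 4.3.3), with TMM scaling, the filterByExpr filter by group and the quasi-likelihood F test. The 8 induction libraries were fitted together, with both target genes kept whatever their counts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Differences between effects (NPC against ESC, line A against line B in total RNA, and nascent against total RNA within each line) were tested as interactions in a fit of all libraries concerned. For retained genes, 10 draws per experiment simulated a return group equal to the control, keeping the control libraries shared. Calls shared between lines were compared with Fisher's exact test, two-sided.

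The 33 gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and, as an alternative, the estimated one. Adjusted p-values are over the lists of a contrast. Beside each are the calls when p-values are adjusted over the list alone. For genes with at most 3 control counts, ratios carry 95% intervals conditional on the sum of both counts, and a count of 0 was replaced by a floor of 3 counts per library. Targeted shares carry 95% Clopper-Pearson intervals, and 38 pairs of libraries were compared by Fisher's exact test with Benjamini-Hochberg adjustment. Classes of neighbouring genes were compared with 100000 permutations of the classes. Gene coordinates are from the count files, and the targeted sequences were placed by matching them to the GRCm38 reference. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the rest.

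The genes named in the text follow a rule. Ezh2 and Eed were looked up in every experiment and Nr2f1 and Foxa1 in every library. In each comparison of loss with control, eligible genes were called, had a symbol other than a predicted model, reached 1 CPM in the higher group and had both libraries of 1 group above both of the other. The 8 largest rises and 4 largest falls were named from these, with up to 4 called genes of smallest adjusted p from each list with at least 2 called members. Up to 5 retained and 5 reversed genes with the smallest adjusted p were added per experiment. For induction, up to 5 called genes per direction other than the target and the genes nearest the target were taken. The text gives a selection of the genes so named, and genes chosen after their values were seen are marked.

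The pipeline was tested on simulated data in which 100 genes per fold size were changed in counts drawn like those of each experiment. For the loss comparison, edgeR recovered 93 of 100 genes at log2 2 and 100 at log2 4 in NPC (16721 genes tested), 83 and 99 in ESC (16722), and 69 and 97 in inhibitor-treated line B (15630). For line A it recovered 61 and 93 in total RNA (17664 genes tested) and 64 and 96 in nascent RNA (18005). For line B it recovered 76 and 95 in total RNA (16889) and 75 and 98 in nascent RNA (17394). It recovered 80 and 99 for induction (14446) and 45 and 82 for the difference between lines A and B (18535). By edgeR between 6 and 24 unchanged genes were called per comparison. In the same simulated data DESeq2 called 53 unchanged genes in inhibitor-treated line B (edgeR 23). It called 51 in line A total RNA (edgeR 11) and 30 in line B total RNA (edgeR 8). There it also recovered more genes at log2 2 (75, 72 and 84 of 100). In NPC and ESC it called 3 and 10 unchanged genes, against 6 and 13 by edgeR. Camera found a simulated list of 30 raised genes in each of the 7 experiments and called 0 of 32 unchanged lists in each. Changes of log2 2 are thus often missed in lines A and B, and a gene not called is not shown to be unchanged.

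Alternatives were RLE size factors, no filter for low counts, no fold threshold, the DESeq2 1.42.0 Wald test, the replicate number as a block, the second count files, the estimated correlation, targeted shares scaled to the fully induced mixture, and each of the 50 libraries left out in turn. Chosen after the data were seen were the block within each guide, each guide's libraries alone, and ESC without Gm42418, Gm26917 and mitochondrial genes. No sample of the series was left out of its comparison. Isoforms and splicing were not analysed, since the files count whole genes.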

Results

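RNA was sequenced from mouse cells in which Polycomb repressive complex 2 (PRC2), whose catalytic subunit Ezh2 methylates histone H3 at repressed genes, was lost and then returned. The comparisons ask which genes become active when PRC2 function is lost, and which of them stay active once it is back. The data hold 50 gene-count libraries in 25 groups of 2, and 16 targeted libraries that count wild-type and mutant reads of Nr2f1 or Foxa1. Neural progenitor cells (NPC), embryonic stem cells (ESC) and immortalized mouse embryonic fibroblasts (MEF) of line B were untreated, treated with 2 µM UNC1999 and 4 µM A395 (inhibitors of PRC2 that act on its enzymatic site and on its Eed subunit), or washed free of the inhibitors. MEF lines A and B were also sampled as wild type, Ezh2 knockout and Ezh2 rescue, as total RNA and as nascent, chromatin-associated RNA. Line A was rescued from a retroviral Ezh2 transgene and line B by reversing the knockout at the endogenous gene. Line B cells with an inducible dCas9-VPR activator and guides at the Nr2f1 or Foxa1 promoter were sampled before and more than 9 days after a transient induction. Total counts per library, in mega-counts (M), were 25.9 to 33.4 M in NPC, 12.5 to 20.9 M in ESC, 14.5 to 21.1 M in inhibitor-treated line B and its controls, and 13.2 to 21.5 M in the induction experiment. In the knockout experiments they were 20.9 to 56.0 M for line A total RNA, 21.0 to 36.9 M for line A nascent RNA, 20.1 to 41.3 M for line B total RNA and 27.1 to 35.3 M for line B nascent RNA. Every group had n = 2 libraries. Levels are CPM (counts scaled to library size) as mean ± SD, and log2 fold changes carry their standard error. Adjusted p-values are from edgeR unless another tool is named. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

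A gene higher after loss (inhibitors or knockout against control) was classed as retained if it was also higher in the return state (washout or rescue) than in the control. It was classed as reversed if it was lower in the return state than after loss and was not called higher than in the control, and as unresolved otherwise. The retained class does not separate a lasting effect of loss from any other difference between return and control. Retained calls share their control libraries with the loss calls, and 2 controls cannot be split into sets of 2. Part of any excess of retained genes over independent lists may therefore come from the shared controls, and the excess is not a measure of a shared effect. A gene without counts in the control is given as at least so many fold higher, against a floor of 3 counts per control library. A gene with 1 to 3 control counts is given as a ratio with its 95% counting interval, which covers counting error only. For lists of related genes, every call by the camera set test was lost when the correlation between genes was estimated rather than preset, and that adjusted p is given beside each result. With only 6 libraries per experiment the estimated version has few residual degrees of freedom and could hardly call any list. Its p-values therefore do not decide whether the calls hold, and the calls rest on the preset correlation.

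In NPC, many genes rose when PRC2 was inhibited. Igf2bp3, an RNA-binding protein of fetal tissues (chromosome 6, 49085223 to 49214957, minus strand, GRCm38), rose from 0.44 ± 0.09 to 90.8 ± 2.67 CPM (log2 7.69 ± 0.20, adjusted p = 2e-08). After washout it was still at 39.5 ± 7.93 CPM (log2 6.49 ± 0.21 against control, adjusted p = 3.2e-07). The zinc-finger transcription factor Plag1 (chromosome 4, 3900996 to 3938423, minus strand) rose from 0.15 ± 0.04 to 15.4 ± 0.74 CPM and stood at 12.6 ± 2.82 CPM after washout. Mybpc1, a myosin-binding protein of muscle, rose as steeply, from 0.24 ± 0.06 to 37.7 ± 0.10 CPM (log2 7.26 ± 0.18, adjusted p = 2e-08), but was back at 0.26 ± 0.01 CPM after washout. Of 17109 genes tested, 2065 rose and 335 fell with the inhibitors. After washout, 407 of the risen genes (19.7%) were retained, 1054 (51%) reversed and 604 unresolved. Groups simulated with no change in the washout gave 0 retained genes in each of 10 draws, and independent lists of the same lengths would share 59.7.

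Ezh2 itself was at 200.1 ± 1.68, 135 ± 0.19 and 191 ± 18.4 CPM in the untreated, inhibitor and washout NPC. The change with the inhibitors, log2 -0.57 ± 0.08, passed the p threshold but not the fold threshold. Eed, which overlaps another annotated gene on its strand and is uncertain because fragments were counted for every overlapping gene, was at log2 -0.61 ± 0.07. Among retained genes, the imprinted gene Zdbf2 rose by log2 4.74 ± 0.15 and kept log2 2.15 ± 0.16. The membrane protein gene Emp1 rose by 3.55 ± 0.11 and kept 2.61 ± 0.11, and Itm2a rose by 3.48 ± 0.11 and kept 2.33 ± 0.11. Tbx3, a T-box transcription factor without counts in untreated NPC, was at least 30.7-fold higher with the inhibitors and at least 18.5-fold higher after washout. Reversed genes included Ism1 (log2 5.48 ± 0.15), the imprinted gene Magel2 (5.82 ± 0.21) and Nrep (1.77 ± 0.07). Tmem200c, Penk, Rgs4 and Neurod4 also reversed after being at least 24.0-fold, 18.7-fold, 18.3-fold and 15.5-fold higher.

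Of 18 measured neuron genes, 11 rose and 7 did not pass, with 11 higher when adjusted over the list alone (camera adjusted p = 4.8e-06; adjusted p = 0.26 with an estimated correlation). They included the neurofilament genes Nefl (log2 7.39 ± 0.33) and Nefm (5.99 ± 0.45) and the tau gene Mapt (2.92 ± 0.22), all retained at lower levels after washout (log2 3.58, 2.99 and 1.92). Of 44 signalling ligands and receptors 25 rose and 1 fell, with 26 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.4e-05; adjusted p = 0.26 with an estimated correlation). The ephrin receptor Epha7 rose by log2 3.46 ± 0.15 and kept 1.64 ± 0.16. Of 87 developmental transcription factors 26 rose and 1 fell, with the same numbers when adjusted over the list alone (camera adjusted p = 0.0027; adjusted p = 0.54 with an estimated correlation). The motor neuron regulator Isl1 rose from 0.10 ± 0.01 to 12.0 ± 0.08 CPM and was at 1.25 ± 0.28 CPM after washout (retained, log2 3.66 ± 0.39). Of 20 imprinted genes 7 rose, 7 when adjusted over the list alone (camera adjusted p = 0.0073; adjusted p = 0.44 with an estimated correlation).

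Glial genes rose as well, 5 of 10, and 5 when adjusted over the list alone (camera adjusted p = 0.0017; adjusted p = 0.27 with an estimated correlation). Gfap (log2 2.84 ± 0.27) and the glutamate transporter Slc1a2 (2.85 ± 0.17) reversed, whereas S100b (2.33 ± 0.17) was retained at log2 2.71 ± 0.17 and the water channel Aqp4 (3.08 ± 0.22) at 1.76 ± 0.24. The cell cycle inhibitor Cdkn1a rose from 89.9 ± 11.9 to 247 ± 22.0 CPM and Cdkn2b by log2 1.87 ± 0.16, and both reversed. Among 23 proliferation genes 1 fell and 22 did not pass, and 1 was lower when adjusted over the list alone. The list's median was log2 -0.64 (camera adjusted p = 1.8e-11; adjusted p = 0.36 with an estimated correlation). Of 22 amino acid and unfolded protein stress genes 6 fell, and 6 when adjusted over the list alone (camera adjusted p = 0.0014; adjusted p = 0.26 with an estimated correlation). The chaperone Hspa5 went from 937 ± 49.1 to 460.2 ± 0.33 CPM (log2 -1.03 ± 0.06). Chac1 changed by -2.05 ± 0.25 and the stress-induced transcription factor Atf3 by -1.36 ± 0.22. Among the largest falls were Ly6c1 (log2 -3.66 ± 0.57), Mxra8 (-2.81 ± 0.23) and Clec14a (-2.76 ± 0.26). Leaving out any of the 6 libraries moved none of the 4 NPC counts by more than 1.5 times. Without the fold threshold the counts were 4360 higher and 4004 lower, with 939 retained and 2328 reversed.

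**Figure D1:**
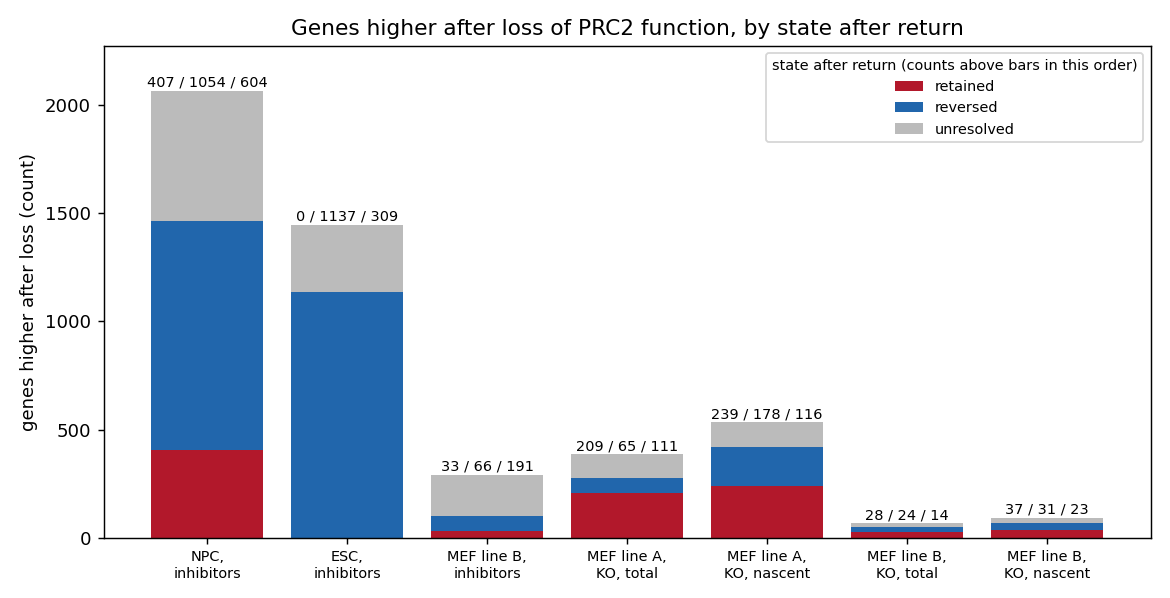
Stacked bars give the number of genes higher after loss of PRC2 function in each of 7 experiments (x axis, n = 2 libraries per condition), split into retained, reversed and unresolved after return. The counts above the bars run from 407 retained of 2065 in NPC to 0 retained of 1446 in ESC, and 209 of 385 in line A total RNA.

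Among ESC genes that passed the filter for low counts, none was called higher after washout of the same inhibitors than in untreated cells. Gas6, a ligand of receptor tyrosine kinases, rose from 12.7 ± 1.5 to 89.5 ± 14.8 CPM (log2 2.81 ± 0.18, adjusted p = 5.6e-05) and was at 13.1 ± 1.52 CPM after washout. Dnmt3l, a cofactor of DNA methyltransferases, went from 12.5 ± 2.98 to 111 ± 37.4 and back to 23.02 ± 0.01 CPM. The pluripotency-associated genes Utf1 (log2 2.15 ± 0.23) and Tdgf1 (1.13 ± 0.16) and the MHC class I light chain B2m (1.44 ± 0.17) also rose and reversed. Gbx2, of the same pluripotency list as Utf1 and Tdgf1, fell, so these genes do not give a direction for that list. The largest falls ended at 0 CPM for the mesoderm regulators T (from 3.72 ± 1.58) and Hand2 (from 1.53 ± 0.47). The Wnt target Sp5 went from 59.1 ± 18.8 to 0.26 ± 0.37 CPM (log2 -7.48 ± 0.67). The imprinted Peg10 fell from 142 ± 81.6 to 3.03 ± 0.28 CPM and the intermediate filament gene Ina from 21.8 ± 0.33 to 0.91 ± 0.07 CPM. After washout they were at 118 ± 16.4 and 22.9 ± 3.94 CPM.

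Ezh2 was at 449 ± 63.0, 305 ± 30.5 and 416 ± 22.7 CPM in untreated, inhibitor and washout ESC. Of 17192 genes tested, 1446 rose and 960 fell with the inhibitors, and 1137 of the risen genes (78.6%) reversed while 309 were unresolved. By edgeR 0 genes were called between washout and untreated ESC, against 994 at an unadjusted p under 0.05; DESeq2 called 0 higher and 16 lower. Simulated unchanged washout groups gave a mean of 0.9 retained genes, at most 3. Without the filter for low counts, 22 genes were retained. Of 12 epithelial genes 6 rose, and 6 when adjusted over the list alone (camera adjusted p = 0.038; adjusted p = 0.71 with an estimated correlation). Epcam (log2 1.99 ± 0.30), Krt18 (1.90 ± 0.29) and Cldn4 (1.20 ± 0.17) were among them. Of 23 proliferation genes 11 fell, and 11 when adjusted over the list alone (camera adjusted p = 3.5e-12; adjusted p = 0.71 with an estimated correlation). They included the mitotic regulators Ccnb1 (log2 -1.48 ± 0.18) and Bub1 (-1.45 ± 0.20). Among 73 developmental transcription factors 3 rose and 15 fell, and the same numbers changed when adjusted over the list alone (camera adjusted p = 0.0092; adjusted p = 0.71 with an estimated correlation). Cdx1 fell from 166 ± 6.98 to 40.5 ± 5.97 CPM, Gbx2 by log2 -2.30 ± 0.19 and Otx2 by -2.24 ± 0.31, while Eomes rose by 1.63 ± 0.22. Of 20 germline genes 7 fell, 8 when adjusted over the list alone (camera adjusted p = 0.038; adjusted p = 0.71 with an estimated correlation). Dazl changed by log2 -1.40 ± 0.20, Sohlh2 by -1.76 ± 0.21 and Hormad1 by -2.02 ± 0.25. Igf2bp3, which rose in NPC, fell from 291 ± 45.6 to 117 ± 0.47 CPM (log2 -1.32 ± 0.17).

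The library of ESC with inhibitors, replicate 2, stood apart. Gm42418, a gene that overlaps ribosomal RNA sequence, took 8.59% of its counts. Rmrp, a short structured RNA, was at 2.16 and 582 CPM in the inhibitor libraries and below 1 in the untreated ones, and Rn7sk was at 4.47 and 1277 CPM. Gas6 was at 79.1 and 100.0 CPM in the same libraries. Leaving out that library gave 697 higher genes, 647 of them also called with both, and 497 reversed genes. Leaving out untreated replicate 1 gave 677 higher and 565 reversed, and untreated replicate 2 gave 661 and 536. With each of these 3 left out, 15 to 20 of the 87 named ESC genes no longer passed, Rmrp and Rn7sk among them.

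The difference between the NPC and ESC responses was tested as an interaction, in 1 model of both cell types. The change with the inhibitors differed for 2341 of 20580 genes, being higher in NPC for 1384 and lower for 957; DESeq2 gave 2402. Igf2bp3 changed more by log2 9.05 ± 0.28 in NPC (adjusted p = 1e-09). Zdbf2 (log2 6.11 higher in NPC, adjusted p = 5.3e-08), Emp1 (4.97, adjusted p = 2e-07), Peg10 (5.46, adjusted p = 7.6e-06), Ina (6.68, adjusted p = 4.5e-06) and Cdkn1a (2.35, adjusted p = 4e-06) differed in the same direction. Gas6 (log2 -2.53, adjusted p = 0.0039), Hspa5 (-1.28, adjusted p = 4e-04) and Rtn1 (-3.46, adjusted p = 7.6e-06) changed less or more negatively in NPC. Ezh2 did not differ (log2 0.03, adjusted p = 0.97). The spread between replicates was wider in ESC than in NPC (common biological coefficient of variation 0.2 against 0.08), which limits the differences that pass.

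In MEF line B, some Hox genes and other developmental transcription factors rose with the inhibitors, and several of these stayed high after washout. Hoxb13 (chromosome 11, 96194316 to 96197447, plus strand) had no counts in untreated cells. It stood at 29.4 ± 3.04 CPM with the inhibitors (at least 153-fold higher) and at 5.54 ± 1.69 CPM after washout (at least 28.9-fold higher). Hoxb9 rose from 0.36 ± 0.06 to 20.3 ± 1.5 CPM (log2 5.82 ± 0.31, adjusted p = 0.0011) and Hoxb6 from 0.80 ± 0.08 to 22.0 ± 7.52 CPM. After washout they were at 12.1 ± 2.00 and 42.5 ± 1.06 CPM. The homeobox gene Lbx1 rose from 0.73 ± 0.28 to 70.0 ± 4.39 CPM and Tfap2b, an AP-2 family transcription factor, from 16.0 ± 0.49 to 151 ± 6.63 CPM. Both were retained (log2 6.76 ± 0.32 and 3.60 ± 0.15 against untreated). Igfbp2, a binding protein of insulin-like growth factors, rose from 21.8 ± 4.68 to 550 ± 5.06 CPM (log2 4.66 ± 0.21, adjusted p = 0.0007) and reversed to 46.1 ± 2.25 CPM.

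Ezh2 was at 112 ± 72.9, 125 ± 2.40 and 97.8 ± 32.9 CPM in these groups. Of 16162 genes tested, 290 rose and 158 fell; 33 of the risen genes (11.4%) were retained, 66 (22.8%) reversed and 191 were unresolved. Simulated unchanged washout groups gave a mean of 0.4 retained genes, at most 2, and independent lists would share 0.6. Of 32 Hox genes 10 rose, and 10 when adjusted over the list alone (camera adjusted p = 0.029; adjusted p = 0.43 with an estimated correlation). After washout 7 were higher, and 10 when adjusted over the list alone (camera adjusted p = 6.3e-06; adjusted p = 0.46 with an estimated correlation). Hoxb8 had 1 count in untreated cells and was 299-fold higher with the inhibitors (95% counting interval 53.3 to 11900). Of 74 developmental transcription factors 18 rose and 1 fell, with 26 higher and 3 lower when adjusted over the list alone (camera adjusted p = 3.4e-06; adjusted p = 0.37 with an estimated correlation). Zic2 (log2 3.87 ± 0.35) was retained at 3.40 ± 0.35. In the MHC class I list 4 of 11 genes rose, 5 when adjusted over the list alone (camera adjusted p = 5.3e-05; adjusted p = 0.37 with an estimated correlation). The peptide transporter Tap1 (log2 2.71 ± 0.41) and H2-K1 (1.44 ± 0.22) were unresolved. The MHC class II gene H2-Ab1, at least 43.4-fold higher, reversed. Of 25 fibroblast and mesenchyme genes 4 fell, 6 when adjusted over the list alone (camera adjusted p = 0.0012; adjusted p = 0.44 with an estimated correlation). These were Fn1 (log2 -1.64 ± 0.31), Col6a1 (-1.29 ± 0.21), Col6a3 (-1.08 ± 0.16) and Thbs1 (-1.33 ± 0.22). The Wnt antagonist Sfrp2 went from 1360 ± 211 to 137 ± 14.7 CPM and the cartilage regulator Sox9 changed by log2 -2.22 ± 0.20. Arhgap45 fell from 7.10 ± 0.43 to 0.25 ± 0.01 CPM and stayed low after washout (log2 -5.28 ± 0.43).

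These line B counts needed both inhibitor libraries. Without inhibitor replicate 1, 23 genes rose, 2 fell, 8 were retained and 0 reversed, and without inhibitor replicate 2 the numbers were 26, 4, 10 and 0. In each case 37 of the 55 named genes no longer passed, among them Hoxb3, H2-Ab1, Sfrp2, Tap1, H2-K1, Zic2, Fn1, Col6a1, Col6a3, Thbs1, Sox9 and Arhgap45, while Hoxb13, Hoxb9, Hoxb6, Lbx1 and Tfap2b still did. Retained genes numbered 19 and 15 without washout replicates 1 and 2, with 0 reversed in both cases, and reversed genes numbered 193 and 103 without untreated replicates 1 and 2. Untreated replicate 1 also stood apart in the number of genes detected, 26066 against 22398 in replicate 2. DESeq2 called 457 higher and 329 lower, with 122 retained and 207 reversed.

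In MEF line A, many of the genes that rose with knockout of Ezh2 were retained in the rescued cells. Igf2bp3 rose from 0.19 ± 0.11 to 75.4 ± 9.59 CPM in total RNA (log2 8.55 ± 0.41, adjusted p = 0.0026). After rescue it was at 27.7 ± 5.40 CPM (log2 7.11 ± 0.40, adjusted p = 0.003). Hoxb6 (chromosome 11, 96292476 to 96301569, plus strand) rose from 0.12 ± 0.03 to 42.9 ± 9.66 CPM and stood at 49.4 ± 6.72 CPM after rescue. Hoxb9, without counts in wild-type cells, was at least 566-fold higher in the knockout and at least 165-fold higher in the rescue. The orphan nuclear receptor gene Rorb rose by log2 9.91 ± 0.57 and kept 9.66 ± 0.57, and the cardiac and endodermal regulator Gata4 rose by 4.34 ± 0.42 and kept 4.03 ± 0.42. The collagen crosslinking enzyme Lox rose from 96.7 ± 18.2 to 522 ± 106 CPM and stood at 691 ± 11.3 CPM. Reversed genes included Bche, at least 143-fold higher in the knockout, the ephrin receptor Epha8 (log2 4.39 ± 0.34) and the imprinted gene Phlda2 (4.44 ± 0.62).

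Ezh2 in line A was at 68.9 ± 3.31 CPM in wild type, 53.4 ± 3.39 in the knockout (log2 -0.37 ± 0.18, adjusted p = 0.51) and 387 ± 47.9 in the rescue (2.49 ± 0.19, adjusted p = 0.0049). The position of the deleted part is not given in the sources used here, and counts cover the whole gene body with its introns, so these values do not test the knockout. Of 18131 genes tested, 385 rose and 43 fell in the knockout; 209 of the risen genes (54.3%) were retained, 65 (16.9%) reversed and 111 were unresolved. Simulated unchanged rescue groups gave a mean of 0.1 retained genes, at most 1, and independent lists would share 11.4. The rescue differed from wild type in more genes than the knockout did, with 539 higher and 139 lower. Of 60 developmental transcription factors 14 rose and 1 fell, with 22 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.00019; adjusted p = 0.95 with an estimated correlation). Tfap2b rose by log2 8.99 ± 0.70 and kept 6.81 ± 0.69, and the homeobox gene Msx1 rose by 3.93 ± 0.45 and kept 3.29 ± 0.44. Of 29 signalling genes 5 rose and 1 fell, with 12 higher and 2 lower when adjusted over the list alone (camera adjusted p = 9.2e-05; adjusted p = 0.57 with an estimated correlation). Epha7, with 2 counts in wild type, was 819-fold higher (95% counting interval 226 to 6770), and Bmp6 changed by log2 -3.33 ± 0.48. Of 28 Hox genes 6 rose and 22 did not pass, with 8 higher when adjusted over the list alone (camera adjusted p = 0.29; adjusted p = 0.95 with an estimated correlation). Of 17 imprinted genes 4 rose (camera adjusted p = 0.65), 4 when adjusted over the list alone, and the list's median (log2 -0.18) and mean (0.91) differed in sign. The zinc-finger gene Plagl1 was 841-fold higher over 3 wild-type counts (95% counting interval 287 to 4080) and retained. Gpr149 fell from 6.28 ± 1.21 to 0 CPM and Agmo from 4.94 ± 0.13 to 0.13 ± 0.01 CPM. Both were also lower in the rescue than in wild type.

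These line A calls needed both wild-type libraries: without either of them 0 genes rose, fell, were retained or reversed by edgeR. Without knockout replicate 1 there were 22 falls and 113 reversed genes, and without knockout replicate 2 there were 41 reversed genes. Without rescue replicates 1 and 2 there were 95 and 90 falls with 6 and 18 reversed genes. DESeq2 called 783 higher and 142 lower, with 436 retained and 219 reversed. With the replicate number as a block, edgeR called 665 higher and 122 lower, with 386 retained and 187 reversed.

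In nascent RNA of line A, Igf2bp3 was at 0.36 ± 0.04, 213 ± 16.6 and 69.3 ± 1.45 CPM in wild type, knockout and rescue (log2 9.22 ± 0.25 in the knockout, adjusted p = 1e-04). The axon guidance ligand Efna5 went from 19.04 ± 0.44 to 1235 ± 51.2 and 923 ± 88.2 CPM, and Rorb from 0.69 ± 0.25 to 667 ± 55.0 and 525 ± 79.1 CPM. Hoxb6 rose by log2 9.52 ± 0.43 and kept 9.89 ± 0.43. Hoxb5, without counts in wild type, was at least 53.4-fold and 56.4-fold higher in knockout and rescue. Jakmip2 (log2 8.39 ± 0.40) and Tll1 (5.31 ± 0.40) reversed, and Gpr149 fell from 26.5 ± 8.90 to 0.03 ± 0.04 CPM. Ezh2 was at 252 ± 51.5, 205 ± 67.4 and 572 ± 46.6 CPM. Of 18489 genes tested, 533 rose and 78 fell. After rescue, 239 of the risen genes (44.8%) were retained, 178 (33.4%) reversed and 116 unresolved. Simulations gave 0 retained genes, and independent lists would share 15.5. In the rescue 538 genes were higher and 200 lower than in wild type. Of 24 Hox genes 7 rose, with 9 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.21; adjusted p = 0.77 with an estimated correlation). Of 270 genes higher in both fractions of line A (10.4 by chance), 130 were retained in both and 102 in neither. For a different change in nascent and total RNA of line A, edgeR called 0 genes of 20273 and DESeq2 4. In edgeR 230 were at an unadjusted p under 0.05, fewer than the 0.05 share expected of unchanged genes. The test, which took all libraries as independent, was thus conservative, and its 0 does not show that the fractions changed alike. Without wild-type replicates 1 and 2, 113 and 88 genes rose, 7 and 10 fell, 39 and 37 were retained and 41 and 30 reversed. Falls numbered 38 without knockout replicate 1, and reversed genes 114 without knockout replicate 2 and 65 and 72 without the rescue replicates. DESeq2 called 865 higher and 202 lower, with 439 retained and 283 reversed. The replicate block gave 870, 198, 421 and 304 in the same order.

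**Figure D2:**
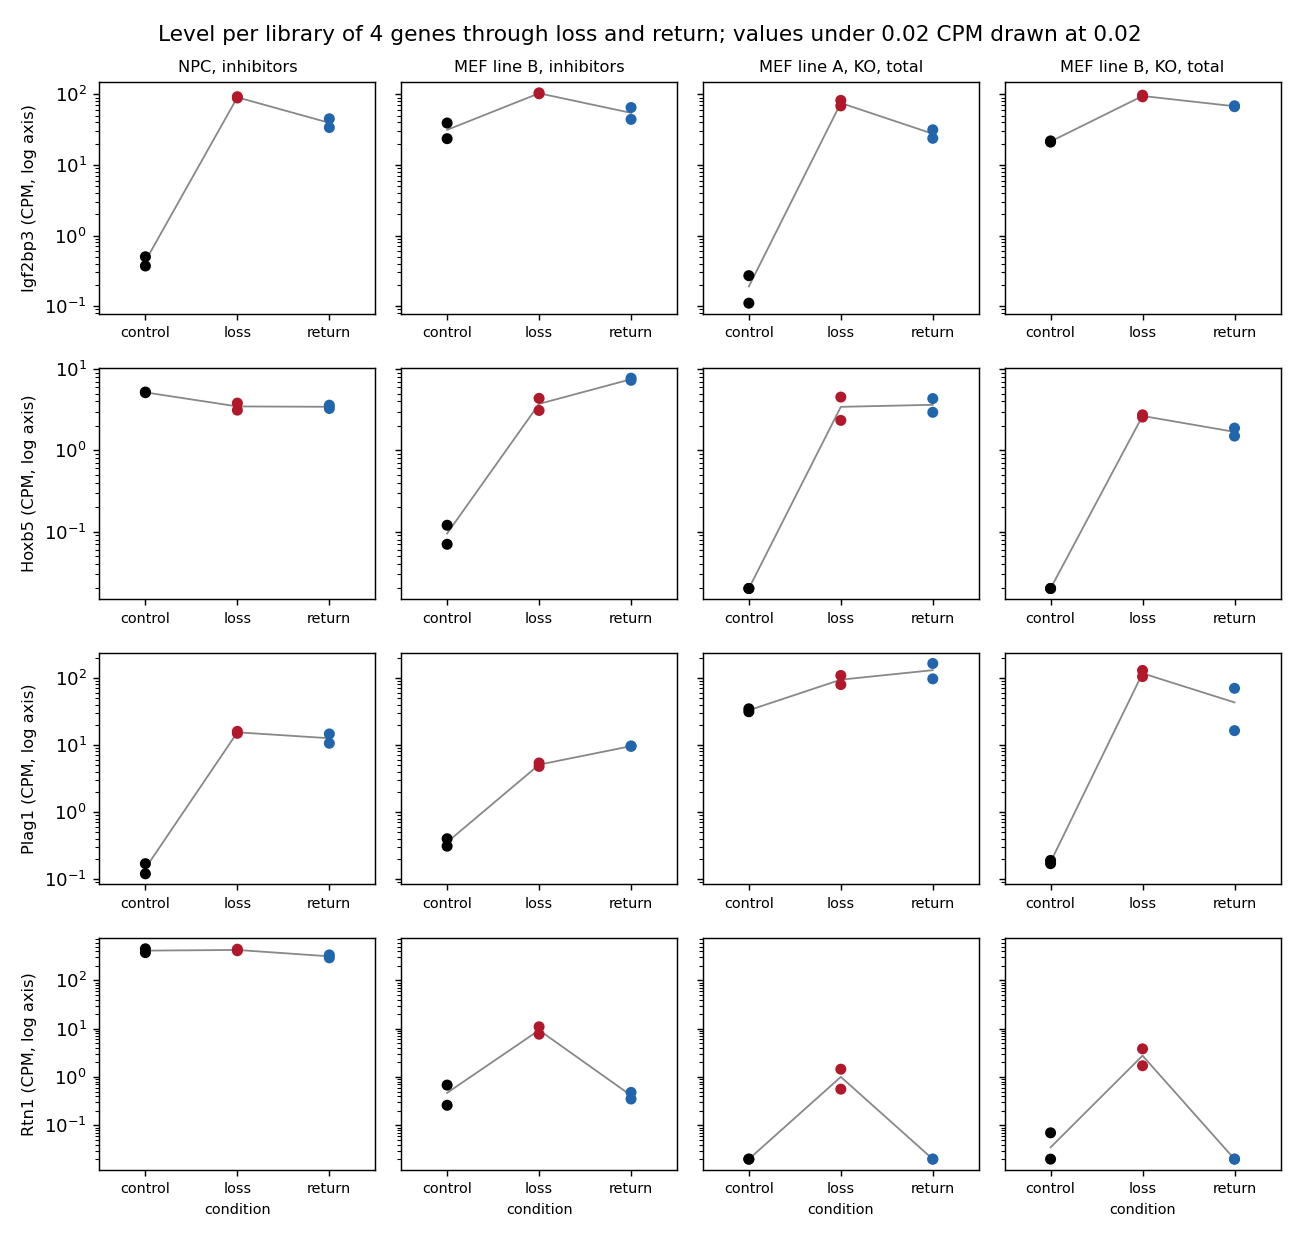
Levels in CPM (y axis, log scale) of Igf2bp3, Hoxb5, Plag1 and Rtn1, chosen after their values were seen, in control, loss and return (x axis) for inhibitor-treated NPC and line B and for total RNA of lines A and B. Each point is 1 library, the line joins group means, and values under 0.02 are drawn at 0.02; Igf2bp3 stays between control and loss levels in all 4 return states, and Rtn1 is at 411 CPM already in untreated NPC.

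In MEF line B, several genes that rose with Ezh2 knockout had few or no counts in wild-type cells. Sp8, a zinc-finger regulator of limb and brain development (chromosome 12, 118846329 to 118852578, plus strand), had no wild-type counts. It stood at 13.5 ± 1.61 CPM in the knockout (at least 126-fold higher) and at 28.1 ± 1.95 CPM in the rescue (at least 263-fold higher). Plag1 rose from 0.18 ± 0.01 to 117 ± 17.4 CPM (log2 9.36 ± 0.96, adjusted p = 0.026) and was at 43.2 ± 37.9 CPM in the rescue, whose libraries differed widely. Hoxb6, with 3 wild-type counts, was 671-fold higher (95% counting interval 229 to 3260; adjusted p = 0.00031) and retained at 17.3 ± 1.1 CPM. Hoxb5 was at least 24.8-fold and 15.8-fold higher in knockout and rescue. Igf2bp3 started from 21.5 ± 0.59 CPM and reached 94.8 ± 3.74 CPM (log2 2.14 ± 0.11), with 67.9 ± 1.41 CPM in the rescue. The kinase gene Sgk3 (log2 4.10 ± 0.30) and the phosphodiesterase gene Pde3b (3.01 ± 0.27) reversed.

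Ezh2 in line B was at 42.4 ± 5.35, 32.1 ± 9.48 and 40.6 ± 4.70 CPM in wild type, knockout and rescue (knockout log2 -0.40 ± 0.23, adjusted p = 0.49), with the same limit on what whole-gene counts can show. Nr2f1, an orphan nuclear receptor gene, had 1 wild-type count and was 403-fold higher in the knockout (95% counting interval 71.8 to 16000; 6.41 ± 0.89 CPM, adjusted p = 0.016) and retained at 8.21 ± 3.40 CPM. The pioneer factor gene Foxa1 had no wild-type counts and was at 4.90 ± 1.76 CPM in the knockout and 1.85 ± 1.90 CPM in the rescue, but did not pass the test (adjusted p = 0.09). In untreated line B cells of the inhibitor experiment Nr2f1 was at 26.8 and 33.8 CPM of total counts. The line B controls thus did not share a starting level of Nr2f1. In that experiment Foxa1 was at 0 and 0.20 CPM untreated, 5.28 and 4.44 with the inhibitors, and 3.56 and 3.59 after washout. Of 17199 genes tested, 66 rose and 13 fell. In the rescue, 28 of the risen genes (42.4%) were retained, 24 (36.4%) reversed and 14 unresolved, against a simulated mean of 0.4 retained genes, at most 2, and 0.4 for independent lists. The rescue differed from wild type in more genes than the knockout did, with 92 higher and 102 lower. Of 29 Hox genes 4 rose, 7 when adjusted over the list alone (camera adjusted p = 0.0097; adjusted p = 0.5 with an estimated correlation). Of 56 developmental transcription factors 3 rose, with 18 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.0062; adjusted p = 0.38 with an estimated correlation). Formative pluripotency genes rose in 2 of 7 cases, 4 when adjusted over the list alone (camera adjusted p = 5.3e-05; adjusted p = 0.38 with an estimated correlation). The DNA methyltransferase gene Dnmt3a (log2 1.52 ± 0.12) was unresolved. Lin28b, an inhibitor of microRNA processing, was 652-fold higher over 2 wild-type counts (95% counting interval 180 to 5390) and retained. Among the falls, the cartilage proteoglycan gene Acan went from 3.36 ± 0.30 to 0.04 ± 0.01 CPM and Zfp677 from 1.81 ± 0.54 to 0.04 ± 0.01 CPM, and both stayed low in the rescue.

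Every library mattered to the line B counts. This held also for the rescue libraries, which enter the comparison of knockout with wild type only through the shared estimate of spread, the scaling and the filter. The number of risen genes therefore does not measure how strongly line B responded, also not beside line A. Without wild-type replicates 1 and 2, 2 and 1 genes rose and were retained, and 0 fell or reversed. Without knockout replicates 1 and 2, 8 and 1 rose, 4 and 1 were retained, 3 and 0 reversed and 0 fell. Without rescue replicates 1 and 2, 400 and 392 rose, 145 and 142 fell, 180 and 86 were retained and 123 and 135 reversed. Of the 26 named genes, 19 to 22 no longer passed when a wild-type or knockout library was left out, and Foxa1 passed when a rescue library was. DESeq2 called 350 higher and 110 lower, with 141 retained and 116 reversed.

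In nascent RNA of line B, Sp8 was at least 43.5-fold and 82.8-fold higher in knockout and rescue than in wild type, Nr2f1 at least 41.1-fold and 52.2-fold, and Hoxb4 at least 23-fold and 16.1-fold. Hoxb6 rose by log2 8.48 ± 0.25 and kept 7.91 ± 0.25. Rtn1, a reticulon of neurons and endocrine cells, was at least 170-fold higher in the knockout and reversed to 0.10 ± 0.08 CPM. Sgk3 rose by log2 4.38 ± 0.32 and reversed. Lin7a fell from 8.72 ± 0.34 to 0.12 ± 0.13 CPM, Bend4 from 4.35 ± 0.71 to 0.07 ± 0.04 CPM and Lypd6 from 10.8 ± 0.91 to 0.32 ± 0.01 CPM. Ezh2 was at 110 ± 5.58, 118 ± 7.70 and 125 ± 14.1 CPM, and Foxa1 at 0, 1.97 ± 0.36 and 0.93 ± 0.66 CPM (adjusted p = 0.065 for the knockout, not called). Of 17701 genes tested, 91 rose and 17 fell. In the rescue, 37 (40.7%) were retained, 31 (34.1%) reversed and 23 unresolved, against a simulated mean of 0.4, at most 1, and 0.5 for independent lists. Against wild type, 88 genes were higher and 115 lower in the rescue. Of 27 Hox genes 5 rose, and 5 when adjusted over the list alone (camera adjusted p = 0.17; adjusted p = 0.84 with an estimated correlation). Of 49 genes higher in both fractions of line B (0.36 by chance), 23 were retained in both. For a different change between the fractions, edgeR called 0 genes of 19389 and DESeq2 0. In edgeR 245 were at an unadjusted p under 0.05, again fewer than expected of unchanged genes, so this 0 has the same limit as in line A. Without wild-type replicates 1 and 2, 0 and 1 genes rose, 0 and 1 were retained, and 0 fell or reversed. Without knockout replicates 1 and 2, 35 and 1 rose, 2 and 0 fell, 14 and 1 were retained and 20 and 0 reversed. Without rescue replicates 1 and 2, 439 and 430 rose, 219 and 222 fell, 209 and 104 were retained and 142 and 177 reversed. As in total RNA, the rescue libraries act on the knockout counts only through the shared fit. DESeq2 called 384 higher and 167 lower, with 150 retained and 142 reversed.

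Lines A and B were compared directly. In a test of the difference of the knockout effect in total RNA, 235 of 19204 genes differed, 173 with a higher change in line A and 62 with a lower one. Igf2bp3 rose more in line A by log2 6.42 ± 0.37 (adjusted p = 5.8e-05), as did Plcl2 (7.63, adjusted p = 3.9e-05), Gata4 (4.34, adjusted p = 0.001) and Lox (2.35, adjusted p = 0.018). For Igf2bp3 this went with a far lower wild-type level in line A than in line B, not with a higher level in the line A knockout. Plag1 (log2 -7.84, adjusted p = 0.0048), Pde3b (-3.17, adjusted p = 0.0022) and Camk4 (-3.43, adjusted p = 0.0078) rose more in line B, and Hoxb6 did not differ detectably (-0.83 ± 0.58, adjusted p = 0.85). Nr2f1, which was already at 9.89 ± 1.84 CPM in wild-type line A, also rose more in line B (adjusted p = 0.00074). Of 16091 genes tested in both lines, 15 were higher in both knockouts, where independent lists would share 1.04 (odds ratio 20, Fisher's exact p = 6.9e-14). Of these, 6 were retained in both lines (Chchd7, Igf2bp3, Tmie, Hoxb6, Hoxb5 and Gpr141) and 5 in line A alone (Epha7, Hoxb9, Fam84b, Ccn4 and Flrt1), these lists being named after the values were seen. With 0 retained in line B alone and 4 in neither, an association of retention between the lines did not pass in total RNA (Fisher's exact test, two-sided, p = 0.1). The number of shared retained genes was 2 without line B knockout replicate 1 and 18 without line B rescue replicate 1. Without line A rescue replicate 2 it was 7 and the association passed (Fisher's exact test, p = 0.013). With DESeq2 it was 24 and without the filter for low counts 54, and the association did not pass (Fisher's exact test, p = 1 and 0.34). In nascent RNA 21 genes were higher in both lines, 8 of them retained in both, 4 in line A alone, 0 in line B alone and 9 in neither. There the association passed (Fisher's exact test, unadjusted p = 0.0046), in a test chosen after the result was seen. The 235 became 74 and 87 without line A wild-type replicates 1 and 2, 91 and 61 without line B wild-type replicates 1 and 2, 111 and 96 without line B knockout replicates 1 and 2, and 650 by DESeq2.

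Transient activation asked whether a gene switched on by dCas9-VPR stays on after the activator is gone. Nr2f1 (chromosome 13, 78188973 to 78199757, minus strand) was at 0.32 and 0 CPM before induction with its own guides and at 35.5 and 13.6 CPM more than 9 days after it ended, from 5 to 1016 counts (160-fold, 95% counting interval 68.2 to 493). Foxa1 (chromosome 12, 57540628 to 57546916, minus strand) was at 0.08 and 0 CPM before and 3.56 and 4.98 CPM after induction with its guides, from 1 to 159 counts (108-fold, 95% counting interval 19.1 to 4300). Each target was higher in both libraries after induction than in both before, but over 14716 genes the fitted changes did not pass the adjusted threshold in edgeR: log2 7.20 ± 1.27 for Nr2f1 (unadjusted p = 0.00039, adjusted p = 1) and 6.52 ± 0.90 for Foxa1 (unadjusted p = 0.00013, adjusted p = 1). DESeq2 gave Nr2f1 an adjusted p of 0.0074 and Foxa1 one of 0.34. With the replicate number as a block within each guide, chosen after the data were seen, edgeR gave them adjusted p of 0.22 and 0.84. Without the filter for low counts both targets passed in edgeR (adjusted p = 2.3e-44 for Nr2f1 and 1.6e-10 for Foxa1). Their log2 changes were nearly the same (7.2 and 6.53), so the pass came from another estimate of spread. It is no added evidence for the targets.

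By edgeR 0 genes were called after induction with either guide set, against 51 (Nr2f1 guides) and 165 (Foxa1 guides) at an unadjusted p under 0.05. Both numbers are below the 0.05 share of 14716 genes expected if none changed, so the test was conservative. Without the filter for low counts edgeR called 8 and 75 genes. DESeq2 called 2 and 0, the 2 being Nr2f1 and A830082K12Rik, which overlaps the Nr2f1 promoter region on the opposite strand and went from 0.19 and 0 to 8.15 and 4.63 CPM (named after its values were seen). Other genes near the targets were not called: Fam172a (log2 0.09) beside Nr2f1 and Mipol1 (0.15) beside Foxa1. Arrdc3 (0.20), on the other side of Nr2f1 but far from it (chromosome 13, 80883384 to 80896035), was not called either. Ttc6, the gene nearest to Foxa1 (chromosome 12, 57564113 to 57737928, plus strand), had too few counts for the fit. With Foxa1 guides it went from 0 and 1 counts before to 14 and 9 after (0 and 0.08 to 0.70 and 0.51 CPM). Foxa1 was at 0 CPM in 3 of the libraries with Nr2f1 guides and at 0.05 in the other. Nr2f1 in the libraries with Foxa1 guides was at 2.15 and 1.75 CPM before and at 2.41 and 17.4 CPM after, so replicate 2 after Foxa1 induction stood apart.

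**Figure D3:**
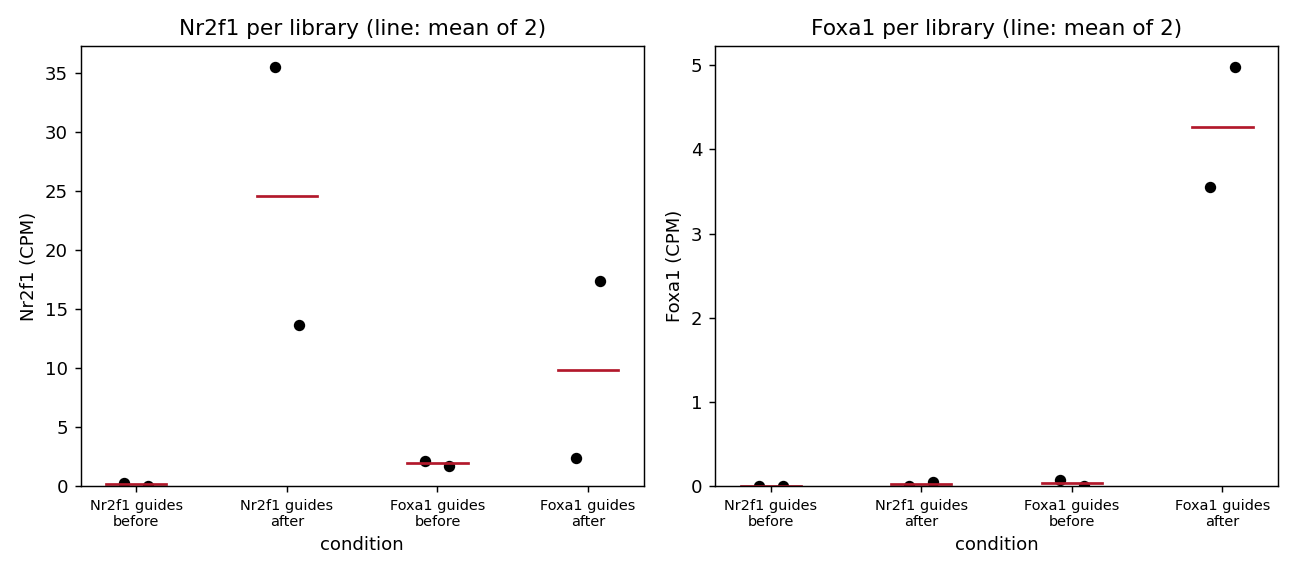
Nr2f1 (left) and Foxa1 (right) in CPM (y axis) in line B libraries with Nr2f1 or Foxa1 guides before and more than 9 days after transient induction (x axis). Each point is 1 library and each line the mean of 2; Nr2f1 reaches 35.5 and 13.6 CPM with its own guides and 17.4 CPM in 1 library with Foxa1 guides.

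Targeted libraries asked whether an active copy of a gene keeps its state beside a silent copy in the same cell. Wild-type cells in which the gene had been induced were fused with mutant cells in which it was off. The share of mutant reads was counted in RNA of each fused clone when uninduced, when induced, and more than 9 days after induction ended. The Nr2f1 reads cover 60 bases of the coding sequence at chromosome 13, 78195596 to 78195655 (GRCm38), in exon 2 of 4 of its 5 transcripts and exon 3 of the other, and the Foxa1 reads 60 bases of coding exon 2 at chromosome 12, 57543257 to 57543316. The first Nr2f1 mutant sequence lacks 1 base. The second is as long as the wild type and differs from it within a stretch of 33 bases, and the comparison does not show what kind of change that is. The Foxa1 mutant sequences lack 8 bases or carry 1 inserted base. There was 1 library per clone and state, so Fisher's exact tests on reads compare libraries, not conditions. Intervals (95%, exact Clopper-Pearson) cover counting error only here too, since PCR reads without molecular identifiers are not independent.

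For Nr2f1, a mixture of RNA from induced wild-type and silent mutant cells gave 1.09% mutant reads (0.869 to 1.35%, 7615 reads) and a mixture with both induced gave 50.5% (49.7 to 51.3%, 14898 reads). Uninduced clone 3 gave 0.023% (0.003 to 0.083%, 2 of 8662 reads) and uninduced clone 9 gave 2.61% (2.29 to 2.95%, 9283 reads), which differed from the silent mixture by -1.07 and 1.52 points (Fisher's exact test, adjusted p = 4.3e-25 and 3.2e-13). Induction brought the mutant share to 48.0% (47.3 to 48.6%, 22854 reads) in clone 3 and 47.1% (46.2 to 47.9%, 12870 reads) in clone 9, below the fully induced mixture by 2.51 and 3.42 points. After induction had ended the shares were 42.0% (40.9 to 43.0%, 8370 reads) and 39.1% (38.1 to 40.1%, 9422 reads), lower than while induced in both clones (-6.02 points, adjusted p = 3.7e-21, and -7.98 points, adjusted p = 2.2e-32, Fisher's exact test).

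For Foxa1, the silent mixture gave 1.61% mutant reads (1.40 to 1.85%, 12233 reads) and the fully induced mixture 21.6% (20.9 to 22.4%, 11487 reads) although it was an equal mixture of both RNAs. Uninduced clones 7-5 and 7-12 gave 1.90% (1.67 to 2.15%) and 1.66% (1.42 to 1.94%), which differed from the silent mixture by 0.29 and 0.05 points (Fisher's exact test, adjusted p = 0.087 and 0.79). The mutant share was 26.5% (25.9 to 27.2%) and 29.6% (28.9 to 30.4%) in the induced clones, and 37.04% (36.4 to 37.7%) and 33.5% (32.8 to 34.1%) after induction had ended. Scaled so that the fully induced mixture reads 50.0%, the shares are 6.56 and 5.77% uninduced, 56.7 and 60.4% induced, and 68.1 and 64.6% after. This scaling assumes that both RNAs of the mixture held Foxa1 at equal levels, which was not tested. The scaled shares therefore do not show that the mutant copy exceeded the wild type. The unscaled share was higher after than during induction in both Foxa1 clones (10.5 points, adjusted p = 3.6e-113, and 3.81 points, adjusted p = 1.4e-13, Fisher's exact test), where it was lower in both Nr2f1 clones. All clones after induction stood far above the silent mixture of their locus.

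**Figure D4:**
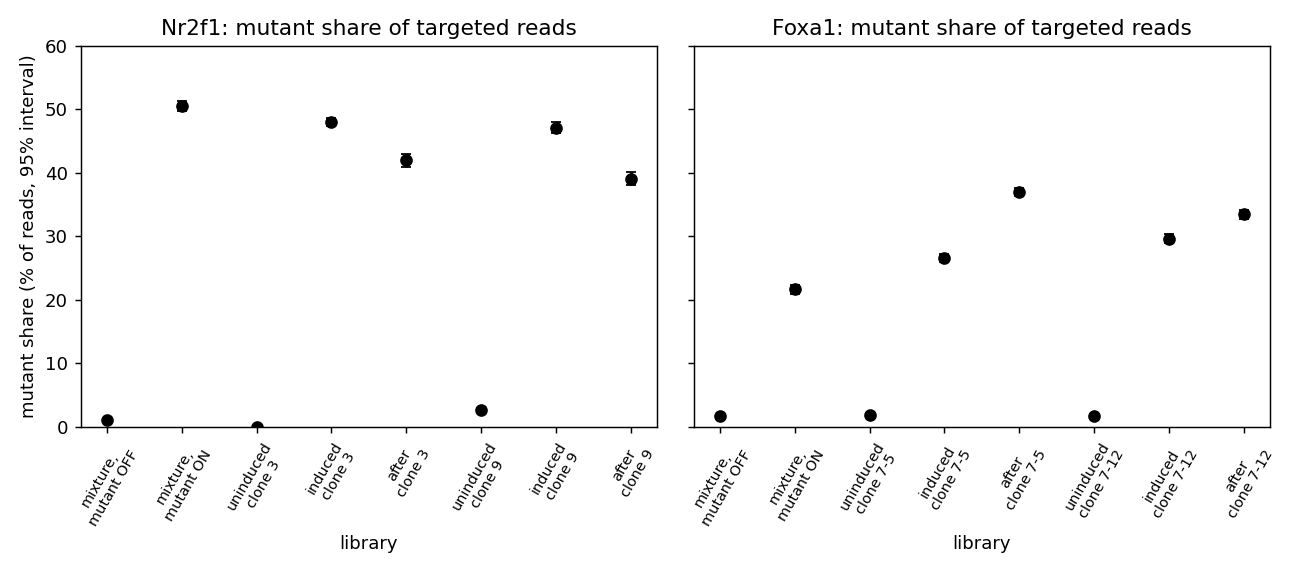
Mutant share of targeted reads (y axis, % with 95% exact interval) for Nr2f1 (left) and Foxa1 (right) in the RNA mixtures and in each fused clone uninduced, induced and after induction ended (x axis, 1 library each). For Nr2f1 the share stays at or below 2.61% in uninduced clones and is 42.0 and 39.1% after induction. For Foxa1, whose equal mixture reads 21.6%, it is at most 1.90% uninduced and 37.04 and 33.5% after. Scaled to that mixture the latter are 68.1 and 64.6%, if both of its RNAs held Foxa1 at equal levels, which was not tested.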

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

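Of the tests in this part, those on the ESC libraries and on neighbouring genes were chosen only after the result was seen.

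A test of the difference itself singled out 2 results: the knockout effect differed between lines A and B for 235 genes in total RNA, and the inhibitor effect differed between NPC and ESC for 2341 genes. Lines and cell types differ in more than their response to PRC2 loss, and no explanation of either difference was tested.

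The ESC library with inhibitors, replicate 2, held more ribosomal and short structured RNA than its partner. If it alone made the ESC calls, genes called without replicate 1 would hardly be raised in replicate 1. The 1609 genes called that way had a median there of log2 1.41 (quartiles 0.85 to 1.97) against washout cells, which excludes that library as the whole cause. Gm42418, Gm26917 and mitochondrial genes took 10.9% of counts in replicate 2 but 0.943% in replicate 1, no more than in untreated cells (1.02 and 1.05%), so counts taken up by them do not explain the rise in replicate 1 either. A response to PRC2 inhibition shared by both libraries remains possible for many of the calls, since 67.6% of these genes reached log2 1 in replicate 1.

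Risen genes within 100 kb of each other often shared their class, retained or reversed, an idea that came from seeing Hoxb genes, Plag1 with Chchd7, and Sox2 with its overlapping transcript together in the class lists. Without pairs that hold any Hox gene or those 4 genes, 72.8% of 294 NPC pairs matched against 59.8% when classes were shuffled (permutation p = 2e-05), and 88.9% of 18 pairs against 63.1% in line A total RNA (permutation p = 0.019). Pairs that do not overlap gave permutation p = 0.00035 in NPC, and 0.00025 when shuffled within quintiles of the rise, so neither fragments counted for several overlapping genes nor similar rises of neighbours are the whole cause there. In line A the same tests gave permutation p = 0.044 and 0.038 on 11 pairs, and 0.063 without 1 of these pairs, which is weak evidence against either. The shared class in NPC thus extends beyond the genes that gave the idea, but a class that follows the chromosomal neighbourhood only restates it. Other causes were not tested, and chromatin shared by neighbours cannot be tested in these RNA data.

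After induction with Foxa1 guides, Nr2f1 was at 17.4 CPM in replicate 2, 70.7% of its mean after induction with its own guides. If RNA or cells with Nr2f1 guides were in that library, other genes specific to those libraries should reach 30% or more of their level there, and under 10% if not. The median of 5 such genes was 21.97% (15.34 to 57.2%, 2 of them over 30%). In the other 3 libraries it was at most 12.5%, but the genes were chosen as low there, so that is no independent reference. As 21.97% lies between the limits of 10% and 30%, the test leaves the question open. Its criterion is a second version, since the first found 0 genes. Nr2f1 may instead have come on in those cells without its guides, for which there was no test.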

How the results depend on the processing

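All tests in this part were planned, except the 3 settings named as added, which were chosen only after the result was seen.

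Each group has 2 libraries, so a library left out leaves 1, which is assumed to vary like the other groups. With RLE size factors all 37 counts and log2 changes kept their side, within 1.5 times. The second count files (4 of 4) and the settings added later (the block within each guide, each guide alone, and ESC without Gm42418, Gm26917 and mitochondrial genes, 4 of 4 each) changed no result either. Counts that moved are given as higher, lower, retained and reversed, and for each the cause was not tested unless stated.

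Without the fold threshold 22 of 28 results stayed within 1.5 times. NPC gave 4360, 4004, 939 and 2328, and ESC 2211 higher and 2126 lower, the threshold being the only change. Without the filter for low counts 28 of 37 results changed. ESC had 22 retained genes. Inhibitor-treated line B gave 816, 474, 197 and 413, line A total RNA 1181, 322, 633 and 370, line B total RNA 800, 332, 312 and 332, line A nascent RNA 1136, 276, 547 and 386, and line B nascent RNA 653, 293, 251 and 263. After induction 8 genes were called with Nr2f1 guides and 75 with Foxa1 guides, and the targets passed (Nr2f1 log2 7.20, Foxa1 6.53). The difference between lines A and B was called for 1223 genes, and that between nascent and total RNA for 27 in line A and 9 in line B.

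With DESeq2 24 of 37 results changed, all of them upwards. In simulated data DESeq2 called more unchanged genes than edgeR in inhibitor-treated line B and in total RNA of lines A and B, though it also recovered more changed ones. Inhibitor-treated line B gave 457, 329, 122 and 207, line A total RNA 783, 142, 436 and 219, line B total RNA 350, 110, 141 and 116, line A nascent RNA 865, 202, 439 and 283, and line B nascent RNA 384, 167, 150 and 142. It called 2 genes with Nr2f1 guides, among them the target (log2 7.25), 650 genes for the difference between lines and 4 for line A nascent against total RNA.

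The labels do not say what a replicate number marks. Of 66 pairs among the 12 groups of lines A and B, 28 correlated over 0.1 (-0.12 to 0.71). Within line A all did, at 0.22, 0.31 and 0.65 in total RNA and 0.19, 0.35 and 0.61 in nascent RNA, a hint of pairing there. Libraries before and after induction correlated at 0.68 with Nr2f1 guides and at 0.15 with Foxa1 guides. In the inhibitor experiment of line B, untreated and washout cells correlated at 0.44, but the inhibitor group gave -0.11 and -0.12 with them. With only 2 numbers per group the samples were taken to share a number and no more. This was settled before calls in the 7 experiments with and without the block were compared, though the block's calls of 0 for induction had been seen beside its correlations. With the replicate block 16 of 37 results changed, 4 downwards. Inhibitor-treated line B had 20 retained and 24 reversed genes, line A total RNA 665, 122, 386 and 187, line B total RNA 117 higher, 21 lower and 40 reversed, line A nascent RNA 870, 198, 421 and 304, and line B nascent RNA 5 lower and 17 reversed. The difference between lines was called for 364 genes.

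Leave-one-out ranges, in the order higher, lower, retained and reversed, were as follows. In NPC they were 1776 to 2194, 248 to 386, 303 to 444 and 816 to 1069, all within 1.5 times. In ESC they were 661 to 1609, 701 to 1049, 0 and 497 to 1306, and in inhibitor-treated line B 23 to 317, 2 to 218, 8 to 32 and 0 to 193. Line A gave 0 to 565, 0 to 95, 0 to 250 and 0 to 113 in total RNA, and 88 to 575, 7 to 100, 37 to 302 and 30 to 196 in nascent RNA. Line B gave 1 to 400, 0 to 145, 1 to 180 and 0 to 135 in total RNA, and 0 to 439, 0 to 222, 0 to 209 and 0 to 177 in nascent RNA. The difference between lines ran from 61 to 340 genes, that between NPC and ESC from 1724 to 2585, and line A nascent against total RNA from 0 to 5. The targets stayed at log2 6.22 to 11.71 (Nr2f1) and 5.67 to 9.22 (Foxa1) with 0 calls. Retained genes shared by lines A and B ran from 2 to 18, and 5 of these settings gave no value. The association turned direction at the value of 2, without line B knockout replicate 1, and passed at 7, without line A rescue replicate 2 (Fisher's exact test, p = 0.013). The shared count of 6 became 24 with DESeq2 and 54 without the filter, but is not among the results counted above as changed, since its association did not pass in either (Fisher's exact test, p = 1 and 0.34).

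Of 3620 values for named genes 486 changed and 8 results in all turned direction, none of them called in either fit. Ezh2 was at log2 -0.37 and 1.04 in inhibitor-treated line B without untreated replicates 1 and 2, and at 0.01 and -0.68 in line A nascent RNA without knockout replicates 1 and 2. Eed was at -0.51 and 0.02 in inhibitor-treated line B without untreated replicates 1 and 2, and at -0.36 and 0.04 in line A total RNA without knockout replicates 1 and 2. In line A nascent RNA it was at 0.05 and 0.03 without wild-type and knockout replicates 2, and at -0.11 without wild-type replicate 1. Nr2f1 was at -0.26 and 0.13 in line A total RNA without wild-type replicates 1 and 2.

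Of 54 list calls for loss against control 0 were left with the estimated correlation, and of those for the return groups 0 as well. With so few libraries per experiment that version could hardly call any list, so this loss does not decide whether the calls hold. Scaling to the fully induced mixture changed 8 of 16 targeted shares, all of Foxa1. It assumes equal levels of the gene in both RNAs of the mixture, which was not tested. The silent and fully induced mixtures became 5.60% and 50.0%, clone 7-5 became 6.56, 56.7 and 68.1%, and clone 7-12 became 5.77, 60.4 and 64.6% (uninduced, induced, after). Shares with unmatched reads in the denominator were planned but not run, since the files give none. The targets had 5 and 1 counts before induction, so counting error alone leaves their ratios between 68.2 and 493 for Nr2f1 and between 19.1 and 4300 for Foxa1.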

Other observations

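Of the tests in this part, the counts of genes shared between experiments and the neighbour tests were chosen only after the result was seen, as were the genes given.

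In line A, some interferon-stimulated genes were higher in the rescued cells than in wild type. Of 26 measured interferon genes 10 were called higher in rescue than in wild type (24 when adjusted over the list alone; median log2 3.13; camera adjusted p = 1.9e-20; adjusted p = 0.79 with an estimated correlation, which was 0.923). The antiviral genes Oas2 (log2 6.78, adjusted p = 0.0037), Oas1a (5.68, adjusted p = 0.0049) and Mx1 (8.10, adjusted p = 0.027) led, with the nucleic acid sensor Zbp1 (5.15, adjusted p = 0.02), Ifit2 (5.02, adjusted p = 0.032) and Xaf1 (3.47, adjusted p = 0.0049). Bst2 (2.99, adjusted p = 0.025), Ifi35 (1.58, adjusted p = 0.033) and B2m (1.63, adjusted p = 0.014) were also higher. None of these was called in the knockout.

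Against the knockout, 4 interferon genes were higher in the rescue (23 when adjusted over the list alone; camera adjusted p = 2.6e-25; adjusted p = 0.56 with an estimated correlation). In nascent RNA 10 of 26 were higher in rescue than in wild type (23 when adjusted over the list alone; median log2 3.09; camera adjusted p = 2.5e-15; adjusted p = 0.72 with an estimated correlation). Of 11 MHC class I genes 1 was higher in total RNA (6 when adjusted over the list alone; camera adjusted p = 1e-05; adjusted p = 0.79 with an estimated correlation). The line A rescue came from a retroviral transgene, and a response to it was not tested.

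Some genes rose in most experiments, of which total and nascent RNA of a line are not independent, so the 7 experiments cover fewer separate systems. Igf2bp3 was higher after loss in 6 of the 7 and retained in 5, and Hoxb5, Hoxb6 and Plag1 were higher in 5 and retained in all 5. Chchd7 was higher in 5 and retained in 4, and Epha7 higher in 5 and retained in 3. Hoxb9 was higher in 5, retained in 3 and reversed in 2. Rtn1, Cacna2d1 and Tbc1d16 were higher in 5 and reversed in 4, and Csmd3 and Eif4e3 were higher in 4 and reversed in 4.

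Genes higher after loss were shared between experiments with separate libraries. NPC and ESC shared 309 where independent lists would share 97 (Fisher's exact test, adjusted p = 5.2e-85), and NPC and line A total RNA 127 where they would share 26.9. In line B, inhibitors and knockout in total RNA shared 28 where independent lists would share 1 (Fisher's exact test, adjusted p = 1.3e-33), and 7 of them were retained in both.

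The neighbour test was extended to 6 experiments after its first results. With all genes and pairs that do not overlap, the adjusted permutation p was 0.00048 in NPC, 0.017 in line A total RNA, 0.00018 in line A nascent RNA, 0.044 in inhibitor-treated line B, and 0.28 and 0.37 in line B total and nascent RNA. Without Hox genes, Plag1, Chchd7, Sox2 and its overlapping transcript, 2 of 21 pairs were left in inhibitor-treated line B, too few for a test, so its result rests on those genes. In line A nascent RNA 45 pairs were left (permutation p = 9e-05), but 24 of them lie in 1 run of 10 adjacent genes that begins at Gm10048, all reversed. Without that run the permutation p was 0.023 on 21 pairs. In NPC the longest run held 18 pairs, and the permutation p without it was 1e-05 on 215 pairs.

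The mutant reads of each targeted locus come from 2 sequences. The second made up 52.5% of mutant reads while induced and 71.0% after induction in Nr2f1 clone 3, and 63.9 and 61.9% in clone 9, with 68.5% in the fully induced mixture. In Foxa1 it made up 19.3 and 18.2% in clone 7-5 and 15.7 and 15.1% in clone 7-12, with 12.3% in the fully induced mixture.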
